A study of Homo sapiens with 12 samples.

How the data were processed

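RNA from 6 diabetic foot ulcers, 3 samples of diabetic foot skin and 3 of non-diabetic foot skin was measured on Affymetrix Human Gene 2.0 ST arrays, 1 array per sample. Per the series' design text, total RNA with the small RNA fraction was extracted with a column kit, samples with an RNA integrity number above 5 were kept, and 100 to 300 ng of RNA was amplified, labelled with biotin and hybridized. Per the same text, the authors normalized and summarized the signals at gene level in Expression Console. The deposited value table holds the result as log2 signals of 53617 transcript clusters on the 12 arrays. The normalization method and the genome build are not given in the sources used here, and no background or detection value was used here. A second deposited table lists 5872 clusters, 5869 of them outside the sex-linked genes, that the authors called between ulcer and foot skin in Transcriptome Analysis Console 3.0. It gives bi-weight average log2 signals, a linear fold, an ANOVA p-value and an FDR-adjusted p-value for each, computed by the authors. In this table the smallest absolute fold is 2 and the largest adjusted p is 0.0500. Bi-weight means recomputed from the value table differed from the listed ones by 0.005 at most. All per-sample columns were used. Each sample's group is as given per the labels. No pair of arrays held the same values, the smallest root mean square difference between a pair being 0.363.

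Gene symbols come from the authors' table alone, where 4126 clusters outside the sex-linked genes carried a symbol. Of all its symbols 3500 were current in RefSeq (assembly GRCh38.p14), 369 were updated through a RefSeq synonym and 260 were kept as given. This left 3893 named genes. For the 103 genes with several named clusters the one with the highest mean was used, and in 4 of these genes the clusters had opposite signs. Before the data were examined, the plan was to fit 1 cluster per named gene. Because names exist only for clusters chosen by the authors for differing, all 49829 clusters within the range of identifiers that table spans were fitted instead, a change made after seeing the data. The 3785 clusters outside that range were left out. Among the clusters fitted, 1176 held values identical to those of another cluster. XIST, TSIX and Y-linked genes were left out of every step.

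Differences were tested on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment, an adjusted p under 0.05 and a fold change over 2, the threshold the authors state. Ulcer was compared with all 6 skin arrays in a 2-group model, ulcer with each kind of skin in a model of 3 groups sharing 1 estimate of the spread, and diabetic with non-diabetic skin in a model of the 6 skin arrays. Standard errors are the moderated ones of limma. Gene lists for 21 processes and 17 cell types were fixed before the data were examined, and the 27 with at least 3 named members were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other named genes, which were themselves chosen for differing and had a median log2 difference of -1.31 in ulcer versus skin. Fisher's exact test compared the directions of list members with those of the other named genes that passed.

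Named genes followed a rule fixed before the data were examined. It took the 8 largest increases and the 8 largest decreases in ulcer versus skin among genes past the threshold whose ulcer and skin values did not overlap, up to 4 genes of lowest adjusted p per list, and 12 fixed genes, of which 7 had a named cluster. For the other comparisons it took the 5 largest changes each way among genes past the threshold, or the 5 each way with the lowest p where fewer than 10 passed. Long noncoding, small RNA, immune receptor, KIR and HLA genes and antisense transcripts were left out of the rule for the largest changes. So were GSTM1, GSTT1, UGT2B17 and ERAP2, whose levels follow common inherited variants. The rule named 138 genes, and 12 more were named after their values were seen. A few of these genes are not reported here.

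The fits were tested on simulated data in which 100 clusters were changed by 1.5 and 100 by 3 on the log2 scale. In ulcer versus skin 79% and 98% were recovered with 5 false calls, in ulcer versus diabetic skin 54% and 97% with 16, in ulcer versus non-diabetic skin 62% and 93% with 6, and in diabetic versus non-diabetic skin 69% and 98% with 1. In 100 simulations with 1 list shifted by 1 on the log2 scale, camera called that list in 100 and another list in 16. The simulated genes varied independently of each other, so these simulations do not test camera's p-values for genes that vary together.

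Alternatives were median centring, quantile normalization, only clusters above the median signal, averaging the clusters of a gene, a variance trend with robust estimation, array weights, an unmoderated model, all clusters, no fold limit, a test against a fold of 1.5 (treat), other groupings of the arrays, the replicate number as a block, other list tests and leaving out each array. Settings without ulcers B and C, Fisher's exact test of direction, and the scaling, estimated correlation and fry settings of the list tests between the skin groups were added after seeing the data. Figures were drawn with matplotlib 3.10.9.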

Results

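Gene expression was measured in 12 samples of human foot tissue. Of these, 6 were diabetic foot ulcers, which are chronic open wounds of the foot in people with diabetes. Another 3 were samples of foot skin from diabetic donors and 3 were samples of foot skin from non-diabetic donors. Each sample was hybridized to 1 array carrying probes for 53617 transcript clusters, a cluster being the set of probes for 1 gene or transcript locus. Values were log2 signals normalized by the authors, and their median per array lay between 5.69 and 6.04. The ulcers are called A to F here and the skin samples carry the replicate numbers of their labels. The series title names an inflammatory response, DNA repair and the microRNA miR-15b-5p as the subjects of the study. The labels do not state that each sample came from a different person, so p-values measure the spread between these samples. The number of arrays limits the precision of every value.

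The ulcer arrays differed more among themselves than the skin arrays did. Across clusters, each skin array had a mean correlation between 0.978 and 0.982 with the other skin arrays. Ulcers A and C to F had one between 0.919 and 0.930 with the other ulcers, ulcer B included. Pairs of ulcers without B had correlations of 0.944 to 0.975, and pairs of skin arrays 0.975 to 0.984. Ulcer B had a mean correlation of 0.799 with the other ulcers, and its signals had an interquartile range of 1.77 against 2.25 to 2.49 on the other ulcer arrays. On the skin arrays this range was 2.58 to 2.71, so it was narrower on every ulcer array than on every skin array. The deviations of ulcer C from the median of all arrays had an interquartile range of 0.739, the widest after the 1.25 of ulcer B. Counts are therefore also given without ulcers B and C, a choice made after seeing the data.

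Ulcers were compared with the 6 skin samples to find the genes that separate the wound from intact foot skin. SPINK6, an inhibitor of kallikrein-related peptidases, was 183-fold higher in ulcer (log2 difference 7.51 ± 0.28 SE, n = 6 and 6, limma adjusted p = 7.14e-09). S100A12, a calcium-binding protein abundant in neutrophils (transcript cluster 16693409), was 103-fold higher (6.69 ± 0.19, adjusted p = 6.29e-10, the lowest of all clusters tested). The copper-dependent ferroxidase homologue HEPHL1 rose 78.1-fold, the interstitial collagenase MMP1 rose 65.6-fold and the ammonium transporter RHCG rose 46.5-fold. The alarm cytokine IL1A rose 36.2-fold and PTHLH, which encodes a parathyroid hormone-related protein, rose 33.6-fold. SPRR2B, a precursor of the cornified envelope, rose 35.9-fold, and it is uncertain because its family members have near-identical sequences.

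Genes of the upper epidermis, of sweat glands and of pigment cells had the largest decreases. KRT2, a keratin of the upper epidermal layers (transcript cluster 16765017), was 69.4-fold lower in ulcer (log2 difference -6.12 ± 0.55 SE, n = 6 and 6, limma adjusted p = 6.99e-06). The filaggrin relative FLG2 was 36.9-fold lower (-5.21 ± 0.96, adjusted p = 0.0011). The secretoglobin SCGB2A2 fell 43.3-fold, the sweat peptide dermcidin (DCD) 41.5-fold and PIP, a secreted protein of glandular epithelia, 24.3-fold. The melanin synthesis genes DCT and TYRP1 fell 23.6-fold and 18.8-fold, and the lectin CLEC2A fell 24.4-fold. In each of these 16 genes all 6 ulcer values lay on one side of all 6 skin values, which the rule that named them required. Without ulcer B the log2 difference of MMP1 went from 6.04 to 6.88, and that of FLG2 from -5.21 to -6.10 without ulcer A.

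**Figure D1:**
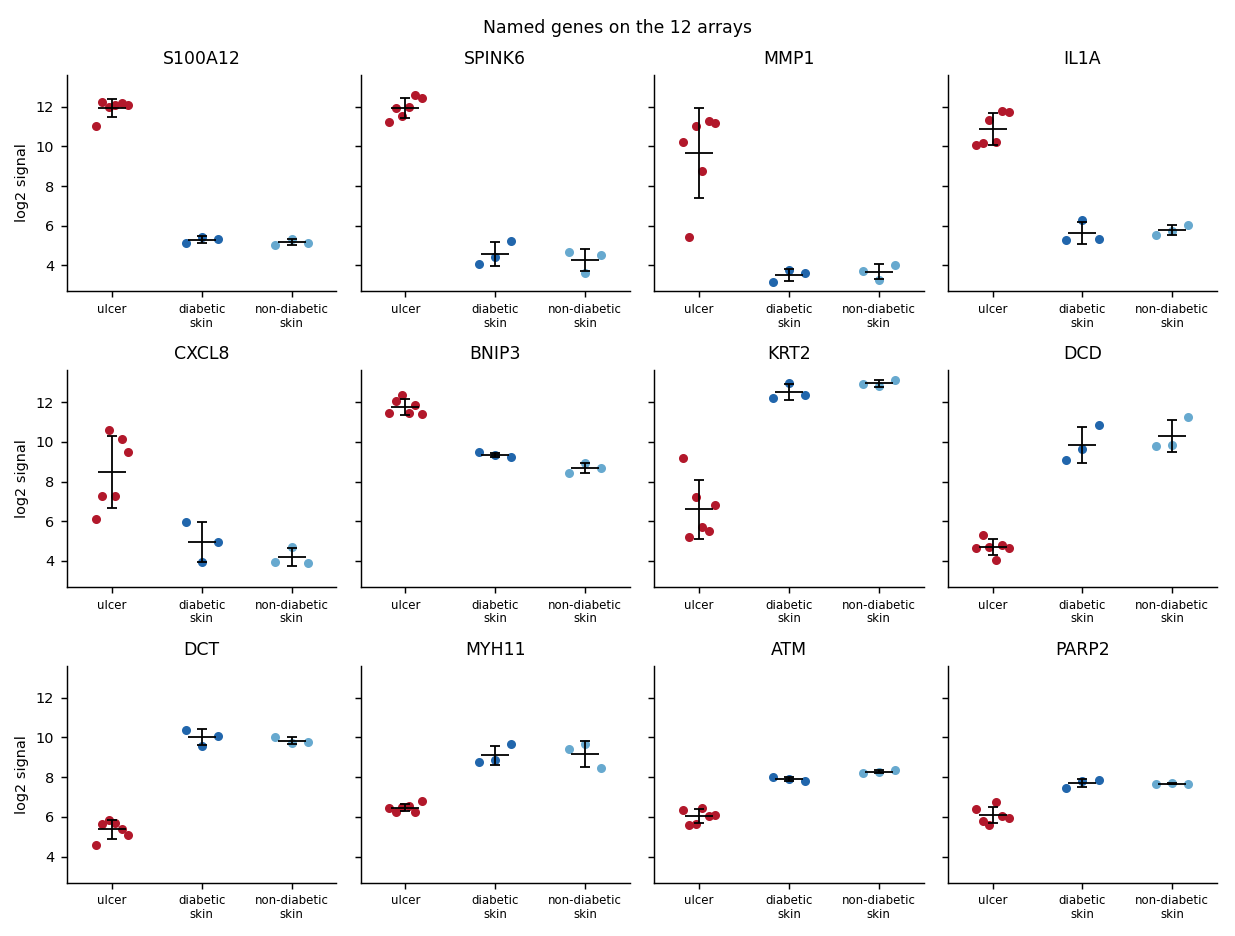
Log2 signal of 12 named genes on the 12 arrays (y axis) by group (x axis: 6 ulcer, 3 diabetic skin and 3 non-diabetic skin arrays), with a dot per array and bars and whiskers for the group mean and SD. S100A12 averaged 11.93 ± 0.45 in ulcer and 5.24 ± 0.16 in skin, and DCD 4.70 ± 0.40 and 10.07 ± 0.80.

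In all, 6993 of 49829 clusters passed an adjusted p of 0.05 and a fold change of 2, of which 1725 were higher and 5268 lower in ulcer (75.3% lower). Without ulcers B and C the count was 6066, of which 71.3% were lower, and 5331 clusters were shared with the full comparison, each in the same direction. The authors' deposited table lists 5869 clusters, of which 4324 are lower in ulcer, and 5462 of them also passed here in the same direction. The median log2 difference of all clusters was 0.23 above 0 in ulcer, 0.11 after centring each array on its median and 0.13 after quantile normalization, while among clusters with a mean above the median of all clusters it was -0.04. With no limit on the fold change 22750 clusters passed and only 38.8% of these were lower, so the excess of decreases held for changes over 2-fold and turned when small changes were counted.

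Gene symbols were known only for clusters of the authors' table, which lists clusters past a threshold in this same comparison. Nearly every named member of a gene list therefore passed by construction, and a list's count informs on its direction only and is no independent evidence that its members changed. Many list members had no named cluster, so counts of named members do not describe whole lists. Named were 3 of 40 cell cycle, 5 of 30 NF-kB and toll-like receptor and 4 of 25 collagen and wound matrix genes. The same held for 3 of 19 monocyte and macrophage and 4 of 14 blood endothelium markers. Of the 3642 named genes that passed, 841 were higher and 2801 lower (76.9% lower), and list counts are to be set against that share. Fry, which tests whether a list's genes move on balance one way and not whether they differ from other genes, called 23 of 27 lists, 7 higher and 16 lower. In each list the same number of members passed adjusted over the list alone as over all clusters. By list means per array, single ulcers lay within the skin range for differentiation (A), collagens and wound matrix (A and D), TGF-beta and BMP (D) and NF-kB genes (E), and all 6 did for lipid barrier and monocyte genes. Ulcer B lay below every skin array for basal keratinocyte, cell cycle and protease genes, although the ulcer mean was higher. Members that went against the rest of their list were named after their values were seen.

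Named keratinocyte genes of the wound edge rose together. All 17 named members of this list, which holds keratins and secreted proteins induced in wounded epidermis, were higher in ulcer, with a median log2 difference of 3.28, and all 17 passed without ulcers B and C. Of them PTHLH rose 33.6-fold, the calprotectin subunit S100A9 rose 32.4-fold (log2 5.02 ± 0.58 SE, n = 6 and 6) and the injury keratin KRT6B rose 15.1-fold. KRT6B shares sequence with its neighbours KRT6A and KRT6C and is uncertain. In camera, a test of a list against the other named genes, the wound-edge list had an adjusted p = 1.52e-11, and adjusted p = 0.177 with an estimated correlation. Of the 4 named basal keratinocyte genes KRT14, SFN and CDH3 rose (2.18-fold, 2.42-fold and 4.12-fold) and the hemidesmosome linker DST fell 3.28-fold, with camera adjusted p = 0.0648, and 0.0477 without ulcer B.

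Named epidermal differentiation genes mostly fell, and 76.9% of all named genes that passed were also lower. Of 15 named members, 12 fell, 2 rose and 1 did not pass, with a median log2 difference of -2.70 that was -2.44 without ulcers B and C and -2.09 without ulcer E. The list mean of ulcer A, 11.54, lay within the skin range of 11.31 to 11.80, and those of the other ulcers lay below it, 7.85 at the lowest. KRT2 fell 69.4-fold and the filaggrin-processing protease ASPRV1 fell 2.77-fold (log2 -1.47 ± 0.20 SE, n = 6 and 6). The cross-linking enzyme TGM1 and its substrate involucrin (IVL), both of the cornified envelope, rose 4.39-fold and 5.85-fold. Of the 8 named genes of the epidermal lipid barrier, 5 rose and 3 fell, among them the sulfotransferase SULT2B1 (3.75-fold higher), the fatty acid elongase ELOVL1 (2.74-fold higher) and the lipase LIPM (6.53-fold lower). Camera adjusted p-values were 0.963 for the differentiation list and 0.0604 for the lipid barrier list, which had 0.0455 without diabetic skin 1.

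Named inflammatory cytokines and chemokines were mostly higher in ulcer. Of 35 genes in this list 13 had a named cluster, of which 10 rose, 2 fell and 1 did not pass. Their median log2 difference was 2.41. IL1A rose 36.2-fold, its antagonist IL1RN rose 4.38-fold (log2 2.13 ± 0.24 SE, n = 6 and 6) and the chemokine CCL20 rose 5.65-fold. The neutrophil chemoattractant CXCL8 rose 15.1-fold (3.92 ± 0.71) and IL1B rose 5.32-fold (2.41 ± 0.51). IL6 missed the fold limit at 1.79-fold (0.84 ± 0.27, adjusted p = 0.0233), while it was past the limit without diabetic skin 1 (1.06 on the log2 scale), with array weights (1.03) and in the authors' deposited table (1.13). The alarm cytokine IL33 fell 6.79-fold and the interferon-induced chemokine CXCL9 fell 6.48-fold. The list had a camera adjusted p = 9.04e-06, and adjusted p = 0.177 with an estimated correlation.

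Named antimicrobial and immediate early genes also rose. All 8 named antimicrobial members were higher, including S100A12 (103-fold), the beta-defensin DEFB103A (25.3-fold, uncertain because of near-identical copies) and the protease inhibitor SLPI (6.55-fold). All 6 named immediate early genes were higher, including the transcription factors FOSL1 (12.8-fold, log2 3.68 ± 0.32 SE, n = 6 and 6) and JUNB (3.69-fold) and the stress gene IER3 (6.88-fold). Camera adjusted p-values were 1.39e-07 and 8.45e-05, with adjusted p = 0.0538 and adjusted p = 0.261 with an estimated correlation. The counts were 8 and 5 without ulcers B and C.

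Named genes of interferon and innate receptor signalling mostly did not rise with the cytokines. Of 10 named interferon response genes, 8 fell, 1 rose and 1 did not pass, while without ulcer B 7 were lower and 2 higher. IFI44 fell 5.92-fold (log2 -2.57 ± 0.26 SE, n = 6 and 6), IFI44L fell 4.62-fold and XAF1 fell 2.40-fold, while the oligoadenylate synthetase relative OASL rose 2.80-fold. Of 5 named genes of NF-kB and toll-like receptor signalling, 3 fell, 1 rose and 1 did not pass, while without ulcer B 1 was lower and 1 higher. TLR3, a receptor for viral RNA, fell 4.14-fold, the kinase subunit IKBKB fell 2.07-fold and the kinase IRAK2 rose 2.23-fold. IKBKB did not pass without ulcer B (-0.96 on the log2 scale), after quantile normalization (-0.79) or with array weights (-0.92), nor IRAK2 without ulcer C (0.99). XAF1 did not pass after quantile normalization (-0.96). Camera adjusted p-values were 0.848 for the interferon list and 0.747 for the NF-kB list, whose camera direction was up while its median was -1.05.

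Leukocyte markers moved in both directions. Of 5 named neutrophil markers, 4 were higher, including S100A12, also in the antimicrobial list, and the chemotactic receptors FPR2 (2.10-fold) and CXCR1 (2.05-fold). The water channel AQP9 was 3.82-fold lower. AQP9 signals were 8.73 to 10.03 in skin, where S100A12 had 5.04 to 5.45, and which cells gave them was not tested. FPR2 signals were low, 4.60 to 5.29 in ulcer and 3.77 to 4.05 in skin, below every array's median. CXCR1 did not pass without ulcer D (0.95 on the log2 scale), ulcer F (0.98) or non-diabetic skin 2 (0.96), and neither receptor passed after median centring (0.95 for FPR2, 0.92 for CXCR1), nor FPR2 after quantile normalization (0.85). The neutrophil list had a camera adjusted p = 0.00385, and adjusted p = 0.177 with an estimated correlation. Of 3 named monocyte and macrophage markers, the lysosomal glycoprotein CD68 rose 5.25-fold (log2 2.39 ± 0.43 SE, n = 6 and 6), and the scavenger receptors CD163 and MRC1 fell 2.42-fold and 2.14-fold. MRC1 did not pass without ulcer B (-0.98) or without diabetic skin 3 (-0.97) or non-diabetic skin 3 (-0.88). The median of that list was -1.10 and its camera direction up (adjusted p = 0.629). All 3 named mast cell markers fell, namely KIT (7.07-fold), HPGDS (3.36-fold) and MS4A2 (3.22-fold). The lists for T and NK cells (20 genes) and for B and plasma cells (14 genes) had no named member, so their genes were not analysed here.

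Named DNA repair genes were mostly lower in ulcer. Of 98 genes in both repair lists, 30 had a named cluster, of which 28 fell, 1 rose and 1 did not pass, with a median log2 difference of -1.55. In repair of strand breaks the kinase ATM fell 4.18-fold (log2 -2.06 ± 0.17 SE, n = 6 and 6), the nuclease MRE11 fell 3.27-fold and the helicase FANCM fell 2.92-fold. In excision and mismatch repair PARP2 fell 3.02-fold (-1.59 ± 0.18) and PMS1 fell 2.61-fold. The ligase LIG4 rose 2.20-fold, and it did not pass without ulcer E (0.97 on the log2 scale) or ulcer F (1.00). With both lists pooled, the share of decreases was higher than among the other named genes that passed in Fisher's exact test (two-sided p = 0.00717, not adjusted). This test was chosen after seeing the data and treats genes as independent. For each list alone, adjusted over all lists, Fisher's exact test gave adjusted p = 0.728 for strand-break repair and 0.126 for excision and mismatch repair. Camera gave adjusted p = 0.209 for strand-break repair and 0.0979 for excision and mismatch repair, and 22 repair genes were lower without ulcers B and C.

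Predicted or reported targets of the miR-15 and miR-16 microRNA family and cell cycle genes were examined because the series title names miR-15b-5p. Of 10 named family targets, 8 fell and 2 rose, a share of decreases that did not differ from that of the other named genes (Fisher's exact test, two-sided p = 1). The cyclin CCND1 fell 3.01-fold (log2 -1.59 ± 0.20 SE, n = 6 and 6), the survival gene BCL2 fell 3.00-fold and IKBKB fell 2.07-fold, while the cyclin CCNE1 rose 3.60-fold and the angiogenic factor VEGFA 2.46-fold. The checkpoint kinase WEE1 fell 2.59-fold (-1.38 ± 0.44, adjusted p = 0.0226), and it did not pass without ulcer B (-0.98) or after quantile normalization (-1.26, adjusted p = 0.0662). SMC4, a condensin subunit whose gene hosts the microRNA miR-15b, fell 3.12-fold. The microRNA itself had no named cluster and was not analysed here. Of 3 named cell cycle genes CCNE1 and the anaphase activator CDC20 rose (3.60-fold and 2.19-fold) and the spindle gene TPX2 fell 2.40-fold. CDC20 did not pass without ulcer E (0.95 on the log2 scale), nor did TPX2 (-0.99) or IKBKB (-0.96) without ulcer B or with array weights (-0.97 and -0.92), nor IKBKB after quantile normalization (-0.79). Camera adjusted p-values were 0.848 for the targets and 0.192 for the cell cycle.

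Named hypoxia and glycolysis genes mostly rose. Of 11 named members 10 rose and 1 did not pass, with a median log2 difference of 2.38. The vasoactive peptide gene ADM rose 9.15-fold (log2 3.19 ± 0.29 SE, n = 6 and 6), hexokinase HK2 rose 8.82-fold and the mitophagy receptor BNIP3 rose 6.71-fold. The list had a camera adjusted p = 7.06e-08, and adjusted p = 0.177 with an estimated correlation.

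Named matrix proteases and inhibitors went in both directions. Of 13 named proteases and inhibitors, 8 rose, including MMP1 (65.6-fold) and the urokinase receptor PLAUR (11.3-fold, log2 3.50 ± 0.37 SE, n = 6 and 6), and 5 fell, including the matrilysin gene MMP7 (9.26-fold), while without ulcer B 3 were lower. That list had a camera adjusted p = 0.0186, but adjusted p = 0.0674 among clusters with a mean above the median, 0.608 with an estimated correlation and 0.254 in fry. Of 25 genes of collagens and wound matrix 4 had a named cluster. All 4 fell, among them versican VCAN (4.79-fold), COL1A2 (2.74-fold) and SPARC (2.22-fold), with camera adjusted p = 0.728. SPARC did not pass without ulcer B (-0.90 on the log2 scale), after quantile normalization (-0.98) or with array weights (-0.86), and 2 of these 4 passed without ulcers B and C.

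Named growth factor, TGF-beta and Wnt genes were mostly lower in ulcer, but so were 76.9% of all named genes that passed. Fisher's exact test of direction called none of these lists. Named were 10 of 30 growth factors and receptors, 10 of 27 TGF-beta and BMP genes and 7 of 35 Wnt genes. Of 10 named growth factors and receptors 8 fell, including IGF1 (3.39-fold, log2 -1.76 ± 0.13 SE, n = 6 and 6), the keratinocyte growth factor FGF7 (4.13-fold) and its receptor gene FGFR2 (5.76-fold), and 2 rose, among them TGFA (3.55-fold). Of 10 named genes of TGF-beta and BMP signalling 8 fell, including the co-receptor TGFBR3 (mean log2 signal 6.71 ± 0.28 SD in ulcer and 9.71 ± 0.38 in skin) and the signal transducers SMAD5 (2.83-fold) and SMAD1 (2.11-fold), and the ligands TGFB1 and BMP2 rose (3.51-fold and 3.47-fold). All 7 named Wnt genes fell, including the co-receptor LRP6 (3.88-fold), the secreted antagonist SFRP2 (8.11-fold) and the receptor FZD4 (2.39-fold). Camera adjusted p-values were 0.686, 0.848 and 0.223. SMAD1 did not pass without ulcer C (-0.97 on the log2 scale) or with array weights (-0.99). BMP4, counted among the decreases at -1.03, did not pass without ulcer A (-0.99), ulcer F (-0.94), diabetic skin 3 (-0.97), non-diabetic skin 1 or non-diabetic skin 3 (-0.94), or after quantile normalization (-0.93), and 4 of the TGF-beta and BMP genes were lower without ulcers B and C.

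Named markers of glands, pigment cells, muscle, vessels and fibroblasts mostly fell beside these groups, and 76.9% of all named genes that passed were also lower. Of 9 named sweat gland markers 8 fell, led by SCGB2A2 (43.3-fold) and DCD (41.5-fold), and the epithelial keratin KRT18 rose 2.02-fold, though it did not pass after median centring (0.89 on the log2 scale) or without ulcer C (0.92), ulcer E (0.98), diabetic skin 1 (0.96), non-diabetic skin 1 (0.96) or non-diabetic skin 2 (0.99). All 7 named melanocyte markers fell, including DCT (23.6-fold) and MLANA (3.42-fold, log2 -1.77 ± 0.19 SE, n = 6 and 6). Of 7 named markers of smooth muscle and pericytes 6 fell and 1 did not pass, with SYNPO2 10.9-fold, MYH11 6.35-fold and RGS5 3.56-fold lower. All 6 named dermal fibroblast markers fell, including APOD (17.6-fold), SFRP2 (8.11-fold) and decorin DCN (6.53-fold). All 4 named blood endothelium markers fell, namely EMCN (3.56-fold), CDH5 (2.37-fold), VWF (2.18-fold) and TEK (2.09-fold), and 2 of them passed without ulcer B. VWF did not pass after quantile normalization (-0.88 on the log2 scale), nor TEK without ulcer B (-0.99), ulcer C (-0.96), diabetic skin 3 (-0.99) or non-diabetic skin 2 (-0.93), or with array weights (-0.98). Camera adjusted p-values were 0.124 for sweat gland, 0.0683 for melanocyte, 0.113 for smooth muscle, 0.255 for fibroblast, 0.555 for endothelium and 0.471 for mast cell markers.

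Lists with fewer than 3 named members were not tested as lists. The Langerhans cell markers CD207 and FCER1A fell 2.79-fold and 4.71-fold, the lymphatic marker MMRN1 fell 3.12-fold and the adipocyte marker FABP4 fell 6.33-fold. The Schwann cell marker CDH19 fell 3.08-fold, and the nerve marker SCN7A, at -0.97 on the log2 scale, did not pass. SCN7A passed after median centring (-1.09) and quantile normalization (-1.13), with array weights (-1.19), and without ulcer B (-1.05), ulcer D (-1.04), diabetic skin 1 (-1.16) or diabetic skin 2 (-1.12), and the authors' deposited table lists it at -1.07. Of the muscle genes ACTN2 and NEB the first rose 2.00-fold and the other fell 3.87-fold, and of the follicle keratins KRT75 rose 15.6-fold (log2 3.97, and 4.57 without ulcer B) and KRT73 fell 4.69-fold. The globin genes HBB and HBM rose 2.29-fold and 2.05-fold, and the ribosomal protein genes RPL37 and RPLP1 fell 2.45-fold and 2.42-fold. HBM and ACTN2 did not pass after median centring (0.92 and 0.88 on the log2 scale), and HBB and ACTN2 did not after quantile normalization (0.99 and 0.85), nor ACTN2 with array weights (0.87). HBM also did not pass without ulcer C (0.96), ulcer E (0.94), ulcer F (0.99) or diabetic skin 1 (0.98). ACTN2 did not pass without ulcer A (0.98), B (0.90), C (0.97) or E (1.00), without diabetic skin 1 (0.96) or 3 (1.00), or without non-diabetic skin 1 (0.99) or 3 (0.97).

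**Figure D2:**
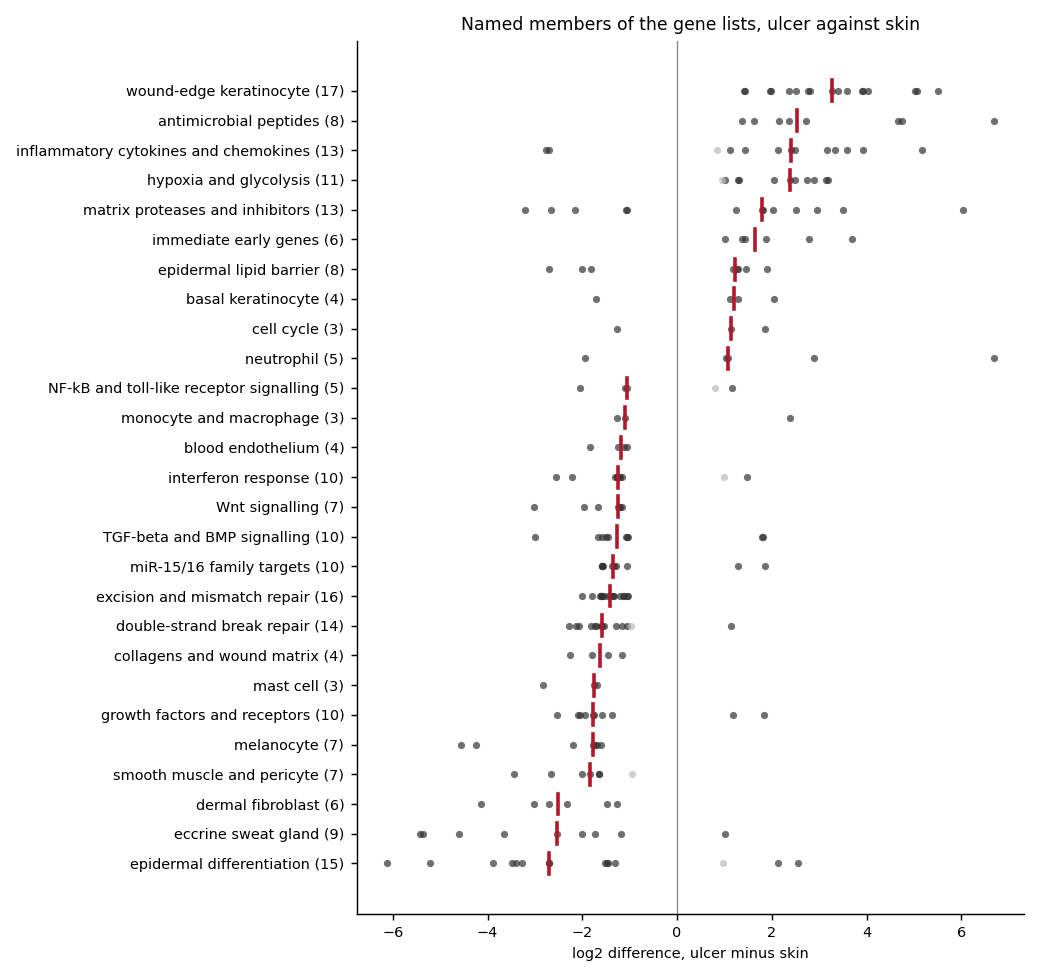
Log2 difference of ulcer minus skin (x axis) for each named member of the 27 gene lists with 3 or more named members (y axis, number of named members in brackets), with a dot per gene, dark where it passed, and red bars for list medians. All 17 wound-edge keratinocyte genes and all 8 antimicrobial genes lay above 0, and all 7 melanocyte and all 7 Wnt genes lay below it.

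Ulcers were next set against each kind of skin, with diabetes held constant in the first comparison. Against diabetic skin SPINK6 was 165-fold higher (log2 7.36 ± 0.35 SE, n = 6 and 3, limma adjusted p = 7.69e-07), followed by S100A12 (99.5-fold), MMP1 (69.2-fold), HEPHL1 (61.1-fold) and RHCG (40.1-fold). KRT2 was 59.6-fold lower (-5.90 ± 0.69), followed by FLG2 (38.4-fold), DCD (35.5-fold), SCGB2A2 (31.5-fold) and DCT (log2 -4.65 ± 0.27). In total 5399 clusters passed, 1270 higher and 4129 lower (76.5% lower). With each array centred on its median 787 were higher and 4633 lower (85.5% lower), and without diabetic skin 3 832 were higher. With no limit on the fold change 6327 were higher and 5641 lower (47.1% lower). Without ulcer B the log2 difference of MMP1 went from 6.11 to 6.95, and that of FLG2 from -5.26 to -6.15 without ulcer A.

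Against non-diabetic skin SPINK6 was 202-fold higher (log2 7.66 ± 0.35 SE, n = 6 and 3, limma adjusted p = 6.49e-07). It was followed by KRT6C (141-fold, uncertain because of its near-identical neighbours), S100A12 (107-fold), HEPHL1 (100-fold) and S100A9 (82.0-fold). KRT2 was 80.8-fold lower (-6.34 ± 0.69), followed by SCGB2A2 (59.5-fold), DCD (48.5-fold), FLG2 (35.5-fold) and PIP (33.6-fold). In total 6878 clusters passed, 1837 higher and 5041 lower (73.3% lower). With each array centred on its median 1125 were higher and 5695 lower (83.5% lower), and with no limit on the fold change 8475 were higher and 6901 lower (44.9% lower). FLG2 went from -5.15 to -6.04 on the log2 scale without ulcer A. Both comparisons used the same ulcer arrays, and whether a gene's change differed between them is the comparison of the skin groups.

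Diabetic and non-diabetic foot skin were compared to see how intact skin differed between diabetic and non-diabetic donors. Of 17 named wound-edge keratinocyte genes 16 were higher in diabetic skin, with a median log2 difference of 1.43. The list mean per array was 8.88 ± 0.66 (SD, n = 3) in diabetic skin, 7.31 ± 0.45 (n = 3) in non-diabetic skin and 11.33 ± 0.25 (n = 6) in ulcer. Of these genes S100A9 was 6.39-fold higher (2.68 ± 0.44 SE, n = 3 and 3), and KRT16 and KRT6A, named after their values were seen, were 4.75-fold and 5.64-fold higher. The log2 signals of KRT6A were 9.52, 7.42 and 9.04 in diabetic skin 1 to 3 and 5.55 to 6.66 in non-diabetic skin. KRT6B, of the same list, did not separate the skin groups. Its signal in diabetic skin 2, 6.29, lay below every non-diabetic one, 7.05 at the lowest, while diabetic skin 1 and 3 lay above them all. KRT6A is uncertain because it shares sequence with KRT6B and KRT6C. Adjusted over the list alone 9 of the 17 passed the threshold, while over all clusters none did. The list had a camera adjusted p = 5.04e-12 and, with an estimated correlation, adjusted p = 0.272.

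Camera with the preset correlation called 4 further lists, of barrier, defence and hypoxia genes, as higher in diabetic skin, and none of these calls held with an estimated correlation. Median log2 differences were 0.41 for the lipid barrier (8 of 8 named genes higher, adjusted p = 7.32e-05), 0.37 for hypoxia and glycolysis (10 of 11, adjusted p = 7.32e-05), 0.28 for antimicrobial genes (7 of 8, adjusted p = 0.00798) and 0.13 for epidermal differentiation (12 of 15, adjusted p = 0.00262). With an estimated correlation these had adjusted p = 0.575, 0.254, 0.272 and 0.388, and fry called none of the lists. No member of these 4 lists passed adjusted over the list alone. The differentiation list had adjusted p = 0.0658 without non-diabetic skin 3. In the main fit no list of dermal cells or matrix was called, and medians were -0.70 for dermal fibroblast (0 of 6 higher in diabetic skin), -0.64 for mast cell (0 of 3), -0.56 for collagen and wound matrix (0 of 4), -0.34 for blood endothelium (0 of 4) and -0.10 for smooth muscle genes (2 of 7). With the replicate block and in the 3-group model 2 lists were called lower, which are not named here.

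No single cluster passed between the skin groups in limma, with or without the fold limit. At an unadjusted p under 0.05 there were 2960 clusters against 2491 that chance gives, the lowest adjusted p was 0.689, and the unmoderated model and the test against a fold of 1.5 also called 0. The named genes with the lowest p in each direction were the Kazal-type inhibitor SPINK7 (log2 1.94 ± 0.30 SE), S100A9 (2.68 ± 0.44), the sodium channel subunit SCNN1G (1.05 ± 0.18), TMEM45B (0.79 ± 0.14) and cystatin CSTA (0.68 ± 0.12) on the higher side. On the lower side were GSTM5 (-1.60 ± 0.23), FAM182A (-1.32 ± 0.23), FAM200C (-0.88 ± 0.15), the pseudogene OR2A20P (-1.11 ± 0.19) and KLHDC1 (-0.76 ± 0.13), all with adjusted p = 0.689. Without diabetic skin 2, IGFL1 was higher (3.11 ± 0.18, adjusted p = 0.0214) and 2 unnamed clusters were lower (-3.60 and -2.18), and without diabetic skin 3, 1 unnamed cluster was higher (4.26). GSTM5 and OR2A20P have close relatives in the genome and are uncertain. Clusters changed by 1.5 on the log2 scale in simulated data of this design were recovered in 69% of cases and those changed by 3 in 98%. Adjusted p-values depend on how many clusters differ, and the simulation changed 100 clusters by each size. These shares therefore do not give the recovery where few clusters differ, and 0 calls do not exclude differences of this size.

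**Figure D3:**
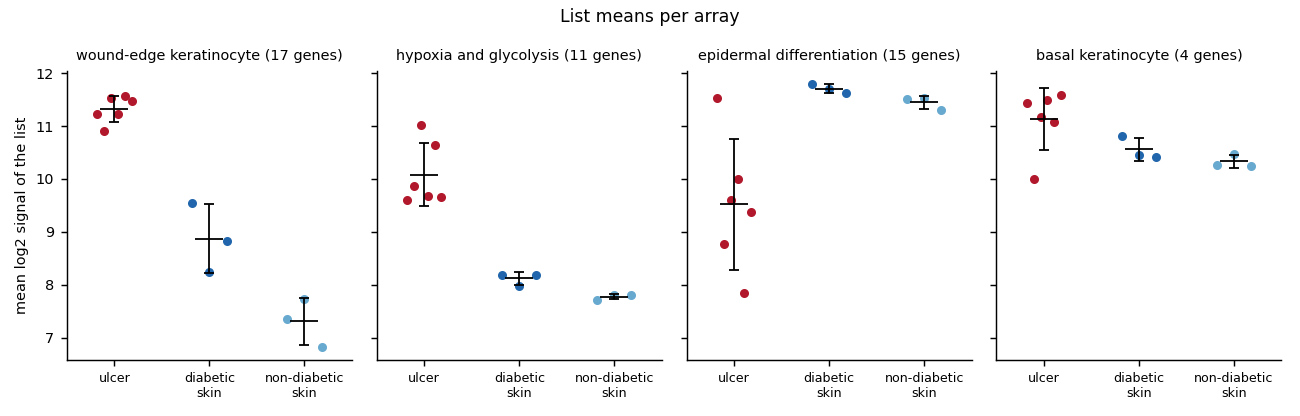
Mean log2 signal of 4 gene lists per array (y axis) by group (x axis: 6 ulcer, 3 diabetic skin and 3 non-diabetic skin arrays), with a dot per array and bars and whiskers for the group mean and SD. Wound-edge genes averaged 7.31 in non-diabetic skin, 8.88 in diabetic skin and 11.33 in ulcer, while epidermal differentiation genes averaged 11.45, 11.71 and 9.52.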

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

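The tests on ulcer B, on the share of decreases and on the amount of epidermis were chosen only after the results were seen. Of 318 groups of 6 values looked at, 21 had a highest or lowest array far from the others by a Dixon-type criterion, which picks about 1 in 20 groups by chance, or 15.9 here. Of the 21, 8 concerned ulcer B, 4 ulcer A, 6 diabetic skin 1, 2 diabetic skin 2 and 1 diabetic skin 3.

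Ulcer B stood apart in the distribution of its signals. Its median log2 signal was 6.04 (5.74 to 5.83 on the other ulcer arrays), its interquartile range 1.77 (2.25 to 2.49) and the interquartile range of its deviations 1.25 (0.458 to 0.739). A change of scale that keeps the order of values is argued against by its highest Spearman's rho with another ulcer, 0.789, which lay below the lowest among the others, 0.941. Its highest correlation with skin, 0.750, lay below the lowest of the other ulcers with skin, 0.846. This cannot decide on a skin sample in its place, since its correlations with the other ulcers also lay below 0.846. It correlated more with the other ulcers (0.773 to 0.810) than with skin (0.724 to 0.750). Its clusters of high signal had a median deviation of -0.94 and those of low signal one of 0.44, against 0.04 to 0.26 and -0.18 to 0.06 on the other ulcer arrays. A narrow interquartile range gives such deviations whatever its cause, so poor RNA or hybridization stays open and cannot be told apart from a difference in the tissue itself, which was not tested.

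In genes, ulcer B had the lowest ulcer signal of CCND1 (7.31 against 8.02 to 8.38), CDH3 (9.78 against 11.34 to 12.19) and IVL (10.19 against 12.03 to 12.71), and the lowest mean of basal keratinocyte genes (10.01 against 11.08 to 11.58). It had the highest signal of OR2A20P (8.84 against 6.74 to 7.37). Ulcer A had the lowest ulcer signal of HEPHL1 (9.35 against 11.64 to 12.58), RHCG (10.25 against 11.80 to 12.23) and S100A12 (11.04 against 11.97 to 12.23), and the lowest mean of antimicrobial genes (11.65 against 12.08 to 12.32).

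Diabetic skin 1 had the lowest skin signal of APOD (8.37 against 9.91 to 10.63) and FANCM (5.66 against 6.06 to 6.26). It had the highest skin signal of FOSL1 (8.03 against 6.31 to 6.61), IL6 (6.99 against 5.43 to 5.92) and TYRP1 (10.90 against 9.57 to 9.99), and the highest mean of melanocyte genes (9.12 against 8.15 to 8.50). Diabetic skin 2 had the lowest skin signal of EMCN (7.14 against 7.74 to 8.11) and the lowest mean of blood endothelium genes (7.34 against 8.04 to 8.42). Diabetic skin 3 had the highest skin signal of MMP7 (9.89 against 7.88 to 8.52).

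Camera with the preset correlation called 5 gene lists as differing in their change from skin to ulcer between the kinds of skin, tested between the skin groups. It called 0 with an estimated correlation (adjusted p from 0.254 to 0.575 for the 5 lists), and fry called 0. Its median on the log2 scale, diabetic minus non-diabetic skin, was 1.43 for wound-edge keratinocyte, 0.41 for lipid barrier, 0.37 for hypoxia and glycolysis, 0.28 for antimicrobial and 0.13 for epidermal differentiation genes. There are too few splits, 10, of the 6 skin arrays to weigh the number of lists, which was 5 in the real split and up to 10 in the others, 5 of the 10 giving as many.

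The wound-edge list was weighed further, although its difference between the skin groups had adjusted p = 0.272 with an estimated correlation and 0.103 in fry. A single skin array as the source is argued against by its median without each array in turn, 1.17 at the lowest, with adjusted p = 1.02e-09 at the highest in camera with the preset correlation. More epidermis in the diabetic samples as the whole cause is argued against because the wound-edge mean, less the mean of differentiation and basal genes, was higher by 1.32 on average and its lowest diabetic value lay 0.38 above the highest non-diabetic one. A different share of epidermis and dermis as part of the cause stays open, since dermal fibroblast, mast cell, collagen and wound matrix and blood endothelium genes had medians of -0.70, -0.64, -0.56 and -0.34 with no member higher in diabetic skin, although camera called none of these lists in the main fit. A difference in skin site stays open and untested, since plantar skin normally makes KRT6A and KRT16 and the site on the foot is not given in the sources used here. Diabetes itself, which the design names, may also account for it and was not tested apart from the site.

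Most clusters past the threshold were lower in ulcer. Among changes over 2-fold the excess stayed after further scaling, with a share of decreases of 70.7% under quantile normalization and 83.9% under median centring. With no fold limit the share was 38.8%. Both scalings were applied to values the authors had already normalized, so they cannot decide whether the authors' own scaling is the cause. The arrays with the widest spread of deviations as the cause are argued against by a share of 71.3% without ulcers B and C. A narrower interquartile range of signals on ulcer arrays (1.77 to 2.49) than on skin arrays (2.58 to 2.71) stays open and was not tested. Fewer glands, pigment cells, vessels and dermal cells in the ulcer samples could also account for the share and cannot be told apart from lower expression. Outside the cell type lists 76.8% of 3588 named genes that passed were also lower, and the lists hold few genes of each cell type.

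Chance is argued against for the number of clusters past the threshold in ulcer versus skin, where 1 of 100 splits, the real one, gave 6993 and the highest of the others 1. It is also argued against for ulcer versus diabetic skin (1 of 84 splits, the real 5399, the highest other 1100) and for ulcer versus non-diabetic skin (1 of 84, the real 6878, the highest other 483). The smallest shares that these splits can give are 0.01 for the first and 0.012 for the other comparisons. Between the skin groups 10 splits are too few, with 0 in the real split and 21 in the highest other, all 10 giving at least as many. For the 7 lists called by camera in ulcer versus skin chance cannot be excluded, since 61 of 100 splits gave as many and the highest other gave 13.

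Among the 3785 clusters outside the range of identifiers in the authors' deposited table, 1285 passed the threshold in ulcer versus skin, and none of these is in that table.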

How the results depend on the processing

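The settings without ulcers B and C, the DNA repair counts, Fisher's exact test of direction and, for the lists between the skin groups, the scaling, estimated correlation and fry settings were chosen after seeing the data. With no fold limit 22750, 11968 and 15376 clusters passed in ulcer versus skin, versus diabetic skin and versus non-diabetic skin, and with the test against a fold of 1.5 the counts were 3287, 1324 and 2301, by construction of these thresholds. In ulcer versus skin camera called 7 lists, 0 with an estimated correlation and fry 23 (7 higher, 16 lower). Between the skin groups camera called 5 lists, 0 with an estimated correlation, 0 with fry and 8 (6 higher, 2 lower) in the 3-group model, and the cause was not tested. The replicate block gave 8 lists (6 higher, 2 lower) and 0 clusters. The numbers shared by the skin samples showed correlations of deviations of 0.098, 0.159 and 0.183, so the samples are taken to share only a number, although each correlated best with its own number, a hint from the data.

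Leaving out 1 array gave 6323 to 7504 clusters in ulcer versus skin, 3685 to 6004 versus diabetic skin, 4849 to 7331 versus non-diabetic skin and 0 to 3 between the skin groups. Lists numbered 7 to 8 in ulcer versus skin and 4 to 7 between the skin groups, and 24 to 29 DNA repair genes were lower. Under the other settings run, total counts stayed within 1.5 times and no called gene or list changed direction. The median difference of all clusters turned from 0.23 to -0.04 in ulcer versus skin among clusters with a mean above the median, since clusters of low signal were left out. Under median centring the higher clusters went from 1270 to 787 versus diabetic skin and from 1837 to 1125 versus non-diabetic skin, and the cause was not tested. Of values of single named genes in ulcer versus skin 2505 kept their side of the threshold, 69 lost it and 12 gained it. For lists these numbers were 564, 9 and 19 in ulcer versus skin and 49, 11 and 0 between the skin groups. Centring on housekeeping genes was not run, since 1 of 15 had a named cluster, nor was the unmoderated model for lists. No background measure was used, so the size of folds against low signals is uncertain, as for MMP1, whose skin mean of 3.61 lay below every array's median.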

Other observations

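The test of the diabetic skin profile against the ulcer profile was written before its result was seen. Of 968 named genes higher in ulcer than in skin 742 (76.7%) were also higher in diabetic than in non-diabetic skin, against 726 of 2925 (24.8%) named genes lower in ulcer. The correlation of both differences across named genes was 0.475, and genes are not independent replicates. There are too few splits, 10, of the 6 skin arrays to weigh it, with 0.475 in the real split and 0.392 in the highest of the others. Both differences use the same skin arrays, and the named genes were chosen by the authors for differing between ulcer and skin.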
